A study of Rattus norvegicus with 15 samples.

How the data were processed

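Polyadenylated RNA was sequenced from 15 cultures of Rat1a, a rat fibroblast cell line. The cultures came from 5 stable lines with 3 biological replicates each, per the labels. A line carried an empty vector (EV), mouse MYC of wild-type sequence (WT), or MYC in which lysine was replaced by arginine at residue 149 (R149), 158 (R158) or 323 (R323). Each construct was represented by 1 stable line, so replicates measured the spread between cultures of a line, and a difference between lines may belong to the line as well as to its construct. RNA was extracted on columns and libraries were made with a stranded dUTP kit that selects mRNA, per the labels' protocols. The submitters' processing notes name TopHat2 2.1.0 and the rat genome build Rnor_6.0. The counting tool, its strand setting and the annotation release are not given in the sources used here. Genes that share reads with near-identical copies, or that overlap on the opposite strand, are therefore uncertain.

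The deposited values were raw counts, whole numbers per gene with no normalization, in 1 table per library. Each table held 32545 rat Ensembl gene identifiers and no summary rows, so unassigned reads could not be examined. Totals ranged from 13303631 to 108933235 counts, and 13676 genes, holding 99.98% of all counts, passed the filter. The files do not pair the identifiers with gene names, and the reference table of rat genes used here carried 0 Ensembl identifiers, so 0 identifiers were paired with a symbol. The 47 gene lists fixed before the data were examined, the level of Myc in each library, and checks of gene length or base composition could therefore not be run. The rule for named genes was changed in the same way. It had asked for the largest changes among genes with adjusted p below 0.05, a mean of at least 1 CPM (counts scaled to a common library total), no overlap between the libraries of the groups compared, and a proper symbol. The symbol was not required here, and the 2 largest rises and 2 largest falls of WT against EV are shown by identifier and followed through every line. Genes are otherwise described as groups.

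Counts were tested with edgeR 4.0.16 in R 4.3.3. Low genes were removed with filterByExpr and its default minimum of 10 counts, libraries were scaled with trimmed mean of M values (TMM) factors, and all 15 libraries entered 1 quasi-likelihood fit with the line as the only term. The 10 contrasts between lines were each adjusted by Benjamini-Hochberg, and a gene was called at an adjusted p below 0.05. The biological coefficient of variation was 16.1%. Fold changes are relative to the other RNAs of a library, because no added standard was stated. Levels are CPM with TMM scaling, given as mean ± SD over 3 libraries. A MYC response score per library was the mean log2 CPM, with a prior count of 2, over genes called with at least 2-fold change against EV in both mutant lines other than the one scored. Genes were thus chosen without the libraries compared, but a gene that WT alone changed cannot enter. Scores were compared with an exact two-sided permutation test, for which 3 libraries against 3 allow no p below 0.1.

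The same procedure was tested on simulated counts with a known set of changed genes, drawn from the real means, library sizes and dispersions. For WT against EV, with 13473 simulated genes tested, it recovered 32.8% of genes changed 1.5-fold, 65.7% of those changed 2-fold and 89.4% of those changed 4-fold, with 5 false calls among 130. For R149, R158 and R323 against WT, 2-fold changes were recovered for 80.6%, 65.7% and 68.7% of genes, with 11 false calls among 141, 8 among 126 and 6 among 130. These shares of false calls were partly above the nominal 5%. Each simulation changed 67 genes by 1.5-fold, 67 by 2-fold and 66 by 4-fold, far fewer than the 3661 genes called for WT against EV. Changes of 1.5-fold were thus often missed at this depth and spread when few genes changed. Where many genes change, the adjusted threshold is looser, so the shares recovered do not carry over to the contrasts with EV. Overlaps between contrasts that share a control were set beside 20 simulated data sets in which the lines did not differ from that control. No pair of replicates agreed within counting noise, with chi-square per degree of freedom between 4.43 and 86.1, so no library was counted as a duplicate.

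The replicate numbers come from the labels, which do not say that equal numbers share a day or batch. Deviations from the group means were correlated between libraries of equal number. The correlation was over 0.1 in every pair for 6 of the 10 contrasts, those among the 4 MYC lines, where it ranged from 0.13 to 0.54. For the 4 contrasts against EV the lowest correlations were 0.099 for WT, 0.017 for R149, 0.084 for R158 and 0.0052 for R323. Counts with the replicate number as a block are therefore given beside the results among MYC lines. Of the 15 libraries, 12 correlated best with libraries of their own number, among them all 5 libraries numbered 1.

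Alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom (limma 3.58.1), other scalings in edgeR, no low-count filter, a filter of 1 CPM in 3 libraries, fits of only the lines compared, the replicate block, each replicate left out, and other prior counts and gene choices for the response score. Alternatives added after seeing the data were replicates 2 and 3 alone, fits without R149 replicate 1 for contrasts that do not use it, WT against EV without R149 replicates 2 and 3, R149 against EV without each WT replicate, left-out EV libraries for WT-regulated genes, other filters and left-out EV or gene-choosing libraries for the response score, every alternative for genes shared by contrasts except library size alone, every alternative for genes called in at least 1, 2 or 3 mutants or distinct to a line, thinning of every library to 13303631 counts, and limma-voom with sample quality weights. Plots were drawn with matplotlib 3.10.9.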

Results

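The data set measured mRNA in Rat1a cells, an immortalized rat fibroblast line, that stably expressed an empty vector, mouse MYC or 1 of 3 MYC mutants. MYC is a transcription factor that binds DNA with its partner MAX. The substitutions replaced lysine with arginine, which keeps the positive charge but cannot be acetylated, in the K149R, K158R and K323R lines (R149, R158 and R323). Each of the 5 lines had 3 replicates. The 3 EV libraries held 19.2, 44.7 and 18.5 megacounts (Mcounts) in genes, and the WT libraries 38.1, 32.8 and 23. The R149 libraries held 37, 43.4 and 109, the R158 libraries 13.3, 29.3 and 16.9, and the R323 libraries 18.3, 33.5 and 20.3 Mcounts. Between 13955 genes (R149 replicate 1) and 17848 genes (R149 replicate 3) had at least 1 count. The introduced Myc could not be read from the tables, because the identifiers were not paired with names, so the labels of the lines were not checked against it.

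The EV libraries lay apart from all 12 MYC libraries on the first principal component, which held 40.3% of the variance. The mean EV position was -60.3 ± 6.42 (SD, n = 3), against 4.5 ± 18.4 for WT, 33 ± 30.1 for R149, 6.76 ± 12.3 for R158 and 16 ± 11.3 for R323. The 4 MYC lines overlapped on this component. Within each MYC line, replicate 1 lay further from EV than replicates 2 and 3, and R149 replicate 1 lay furthest, at 67.8. After all libraries were thinned to the same total, R149 replicate 1 had 13677 genes detected, while the other 14 libraries had between 14871 and 15636. Correlations of log2 CPM between replicates ranged from 0.972 to 0.997.

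**Figure D1:**
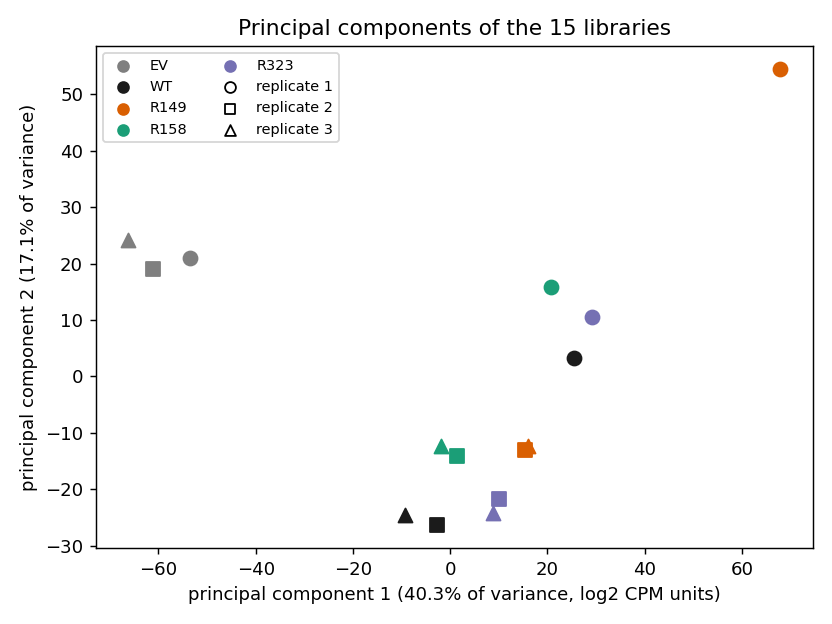
Positions of the 15 libraries on principal components 1 (40.3% of the variance) and 2 (17.1%) of log2 CPM, coloured by line, with the marker giving the replicate number. The 3 EV libraries lie on the left, and R149 replicate 1 lies alone at 67.8 on component 1 and 54.5 on component 2.

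The comparison of WT with EV asked which RNAs differed when wild-type MYC was added. Of 13676 genes tested, 3661 (26.8%) changed, 1728 higher and 1933 lower in WT. The larger changes were mostly falls, since 242 genes rose and 690 fell by at least 2-fold, and 51 rose and 80 fell by at least 8-fold. Genes that rose were most frequent among abundant RNAs, at 19.6% of the most abundant quartile (median 126 CPM) against 4.83% of the least abundant (median 1.06 CPM). Falls made up 13.6%, 18%, 13.9% and 11% of the quartiles from least to most abundant. The quartiles rank the mean level over all libraries, most of them from MYC lines, so a rise itself moves a gene up the ranking. Changes are also harder to call at low counts, and the share of these 2 limits in the gradient was not tested. The gene ENSRNOG00000008465 rose from 0.0577 ± 0.0818 CPM in EV to 16.9 ± 2.39 CPM in WT (SD, n = 3), a log2 fold change of 8.35 ± 0.37 (SE) with an edgeR adjusted p of 5.0e-09. The largest rise was that of ENSRNOG00000052880, from 0.0397 ± 0.0349 to 50 ± 27.8 CPM, with a log2 fold change of 9.94 ± 0.69 and an adjusted p of 3.1e-07. ENSRNOG00000052758 fell from 12.8 ± 2.55 to 0.138 ± 0.035 CPM (log2 fold change -6.49 ± 0.64, adjusted p 6.2e-06), and ENSRNOG00000014979 from 4.7 ± 1.49 to 0.0723 ± 0.0653 CPM (log2 fold change -5.92 ± 0.74, adjusted p 5.7e-05). These fitted folds rest on few counts in the low line, from 4 counts summed over the EV libraries for each rising gene to 13 and 7 counts over the WT libraries for the falling genes. Without EV replicate 3 the number of changed genes was 2399.

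The comparisons of each mutant with EV asked whether MYC with a substituted lysine changed RNA levels too. All 3 mutant lines had genes changed in both directions against EV. In R149, 5264 genes (38.5%) changed, 2495 higher and 2769 lower, with 333 rising and 1247 falling by at least 2-fold. In R158, 3892 genes (28.5%) changed, 1967 higher and 1925 lower, an order that turned in 14 of 19 alternatives (2064 and 2252 with DESeq2, 1555 and 2172 with library size alone), with 240 and 637 by at least 2-fold. In R323, 4076 genes (29.8%) changed, 1933 higher and 2143 lower, with 269 and 886 by at least 2-fold. Among the most abundant quartile of genes, 29.9% rose in R149, 22.9% in R158 and 21.7% in R323, against 5.76%, 5.15% and 4.71% of the least abundant quartile. The limits of these quartiles named for WT apply here as well. ENSRNOG00000008465 rose in every mutant line, to 19.3 ± 1.35 CPM in R149, 16.9 ± 3.03 in R158 and 20.8 ± 3.31 in R323 (SD, n = 3). ENSRNOG00000052758 fell in every mutant line, to 0.738 ± 0.439, 0.158 ± 0.159 and 0.315 ± 0.362 CPM, and ENSRNOG00000014979 fell to 0.233 ± 0.206, 0.996 ± 0.232 and 0.14 ± 0.0892 CPM. The edgeR adjusted p of these falls was at most 0.00923. Without R149 replicate 1, which had few genes detected, 4503 genes changed in R149. For R158 the number was 2488 without EV replicate 2 (1193 higher and 1295 lower) and 2108 without EV replicate 3 (947 and 1161).

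**Figure D2:**
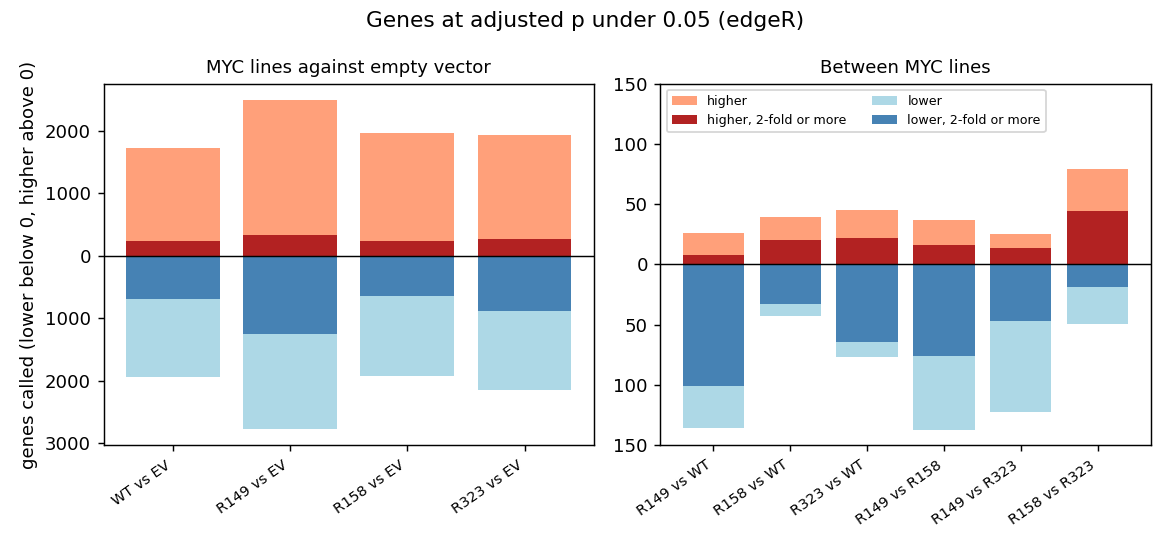
Number of genes called by edgeR at an adjusted p below 0.05 in each of the 10 comparisons, higher above and lower below 0, with dark bars for changes of at least 2-fold. The vertical scales differ: bars against EV reach 2769 genes, those between MYC lines 137.

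The 4 comparisons with EV called many genes in common. In all 4 MYC lines 1019 genes were higher than in EV and 1183 were lower, of 6580 genes called in any line, and 96 rose and 396 fell by at least 2-fold in all 4. Only 19 genes were called in opposite directions in different lines. WT and R149 shared 1458 higher and 1723 lower genes, where independent lists of these sizes would share 315.3 and 391.4. WT and R158 shared 1201 and 1371 (248.5 and 272.1 for independent lists), and WT and R323 shared 1360 and 1550 (244.2 and 302.9). Without EV replicates 2 and 3 in turn, the higher genes numbered 603 and 546 in all 4 lines, 909 and 885 for WT and R149, 710 and 618 for WT and R158, and 828 and 836 for WT and R323. Without EV replicate 3 the lower genes numbered 750 in all 4 lines and 854 for WT and R158, and without WT replicate 1 WT and R149 shared 945 higher genes. Simulated lines without any change shared 0 calls. Such lines are expected to make few calls at all, so this count cannot show what the shared EV libraries contribute. Across genes, which are not independent replicates, the covariance of log2 fold changes with those of WT was 0.515 for R149, 0.431 for R158 and 0.497 for R323, and the shared EV libraries alone gave 0.0409, 0.0411 and 0.0407 in simulation. The correlations were 0.813, 0.796 and 0.815, beside simulated values of 0.521, 0.496 and 0.5. The 3 EV libraries were too few to be split into parts of 2 libraries each, so part of the overlap may come from the shared controls.

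Genes that WT changed by at least 2-fold, 242 up and 690 down, were followed in each mutant line. Of the 242 genes higher in WT, 64.5% were also called higher against EV in R149, 65.7% in R158 and 65.7% in R323. Of the 690 lower genes, 94.6%, 79.1% and 87.7% were also called lower. The sign of the change was the same as in WT for 97.7%, 97.6% and 97.5% of the 932 genes. The median log2 fold change of the higher genes was 1.66 in WT, where they were chosen, and 1.31, 1.22 and 1.29 in R149, R158 and R323. That of the lower genes was -1.56 in WT and -1.79, -1.35 and -1.59 in the mutants.

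The difference between mutant and WT was itself called for few of these 932 genes. In R149, 58 genes differed from WT, 37 of them against the direction of the WT change and 21 further along it. In R158 the numbers were 45, 43 and 2, and in R323 they were 51, 37 and 14. Simulated mutants identical to WT, with 1253 WT-regulated genes on average, gave at most 1 gene against the WT change. They gave at most 2 calls in any comparison with WT, so they cannot show how real differences would split. The simulated libraries had no shared replicate effect and gave more WT-regulated genes than the 932 of the data. Their numbers may therefore be too low a baseline. The WT libraries enter both the choice of genes and the difference from WT, which by construction favours differences against the WT change. Of the genes that moved against it, 30 in R149, 22 in R158 and 26 in R323 were genes that WT had raised. With the replicate number as a block, 138, 97 and 92 of the WT-regulated genes differed in R149, R158 and R323, 68, 91 and 57 of them against the WT change and 70, 6 and 35 further along it. The excess against the WT change in R149 was thus absent with the block, as it was with DESeq2 (56 and 56). Without WT replicate 1 the numbers were 105, 87 and 85. For R149 they were 30, 31, 35 and 33 without WT replicate 2, WT replicate 3, R149 replicate 2 or R149 replicate 3, and for R158 they lay between 15 and 28 without any of the other 5 libraries.

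A score over genes called in both other mutants gave the size of the response that mutants share, which leaves out genes changed by WT alone. For R149, 150 genes raised in the other mutants stood 1.81 ± 0.12 log2 units above EV, and 1.75 ± 0.083 in WT (SD, n = 3), with an exact permutation p of 0.5. The 499 lowered genes stood at -2.26 ± 0.33 in R149 and -1.72 ± 0.34 in WT, with an exact permutation p of 0.3. For R158 the values were 1.59 ± 0.096 against 1.6 ± 0.057 in WT over 178 raised genes, and -1.47 ± 0.17 against -1.5 ± 0.28 over 778 lowered genes. The exact permutation p was 1 and 0.9. For R323 they were 1.83 ± 0.089 against 1.69 ± 0.099 over 167 raised genes, and -1.9 ± 0.14 against -1.62 ± 0.33 over 582 lowered genes, both with an exact permutation p of 0.3. The ranges of mutant and WT libraries overlapped in all 6 comparisons, and 0.1 was the smallest p this design allowed. Over lowered genes, libraries of equal number, compared after the scores were seen, differed by -0.54, -0.48 and -0.61 between R149 and WT, a mean of -0.54 ± 0.065 (SD, n = 3 pairs). R323 was lower than WT in 3 of 3 pairs as well, by -0.28 ± 0.19, and R158 in 1 of 3, with a mean difference of 0.027 ± 0.13. An exact sign-flip test of 3 pairs allows no p below 0.25. Whether replicates 2 and 3 pair by number was not established, so the spread over pairs rests on an assumed pairing. The unpaired difference over lowered genes was -0.33 for R149 without R149 replicate 1 and -0.491 and -0.142 for R323 without WT replicates 1 and 3. Over genes chosen from WT against EV instead, a choice that favours WT, the raised-gene score fell below WT by 0.69 in R149, 0.70 in R158 and 0.64 in R323 (log2), and the lowered-gene difference was -0.208 in R149, 0.291 in R158 and -0.00489 in R323.

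**Figure D3:**
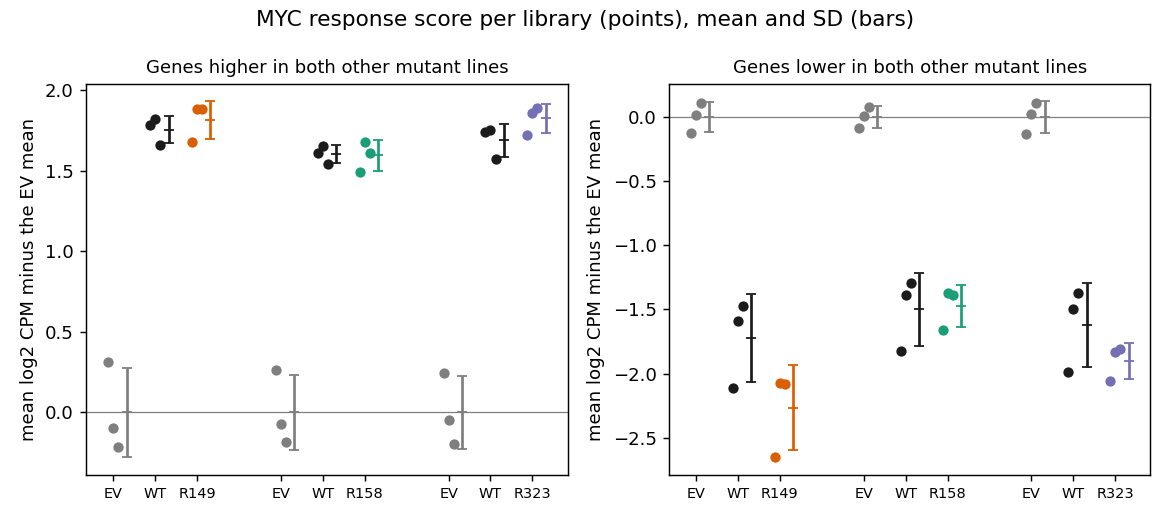
Mean log2 CPM relative to the EV mean over genes raised (left) or lowered (right) against EV in both mutant lines other than the one scored, for each library of EV, WT and that mutant, with mean and SD. Mutant and WT libraries overlap in every panel group, with R149 at -2.26 and WT at -1.72 over lowered genes.

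The comparisons of each mutant with WT asked which RNAs depended on the substituted lysine. They called fewer genes than the comparisons with EV. With replicates 2 and 3 alone, an alternative added after the replicate 1 libraries were seen to stand apart, they called 1323, 996 and 924 genes for R149, R158 and R323. In R149, 162 genes differed from WT, 26 higher and 136 lower, and 101 of the lower genes differed by at least 2-fold. Of these 136 lower genes, 37 had risen in WT against EV, 27 had fallen in WT and were lower still, and 70 were called lower than EV in R149 but not in WT. With the replicate number as a block, 132 genes were called higher and 378 lower. Leaving out WT replicate 1 gave 356 genes, and leaving out WT replicate 2, WT replicate 3, R149 replicate 2 or R149 replicate 3 gave 76, 79, 83 and 76. The 109 genes with at least 2-fold difference became 218 without WT replicate 1, and 62, 60, 68 and 63 without those 4 libraries. With the block they became 196.

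In R158, 82 genes differed from WT, 39 higher and 43 lower, 20 and 33 of them by at least 2-fold. Of the 39 higher genes, 25 had been lowered in WT against EV, and of the 43 lower genes, 24 had been raised. ENSRNOG00000014979 stood at 0.996 ± 0.232 CPM in R158 and 0.0723 ± 0.0653 in WT (SD, n = 3), a log2 difference of 3.66 ± 0.80 with an edgeR adjusted p of 0.052. The blocked fit called 117 genes higher and 127 lower, and placed ENSRNOG00000014979 at an adjusted p of 0.0239, within a range of 4.4e-04 to 0.244 over 18 alternatives, 6 of which called it. The count was 206 without WT replicate 1 and 143 without R149 replicate 1, whose spread enters the fit. It was 33 and 19 without WT replicates 2 and 3, and 45, 23 and 32 without R158 replicates 1, 2 and 3. The 53 genes with at least 2-fold difference became 116, 26 and 17 without WT replicates 1, 2 and 3, and 33, 17 and 24 without R158 replicates 1, 2 and 3. With the block they became 101.

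In R323, 122 genes differed from WT, 45 higher and 77 lower, 22 and 64 of them by at least 2-fold. Of the 77 lower genes, 29 had risen in WT against EV and 14 had fallen in WT and were lower still. Of the 45 higher genes, 18 had fallen in WT. The blocked fit called 144 genes higher and 179 lower. The count was 242 without WT replicate 1, and 61, 64, 65 and 62 without WT replicate 2, WT replicate 3, R323 replicate 2 or R323 replicate 3. The 86 genes with at least 2-fold difference became 157 without WT replicate 1, and 53, 55, 55 and 52 without those 4 libraries. With the block they became 136.

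ENSRNOG00000052880, the largest rise of WT against EV, was lower in all 3 mutant lines than in WT. Its level was 0.0201 ± 0.0189 CPM in R149, 0.074 ± 0.0643 in R158 and 0.0389 ± 0.0673 in R323 (SD, n = 3), and none of these was called different from the 0.0397 ± 0.0349 CPM of EV. The log2 differences from WT were -10.7 ± 0.67, -9.13 ± 0.67 and -9.76 ± 0.69 (SE), with edgeR adjusted p of 3.8e-07, 7.4e-06 and 2.0e-06. With limma-voom the adjusted p was 0.079 for R158 and 0.0513 for R323, the highest over 18 alternatives, whose lowest values were 4.4e-16 and 1.0e-16. ENSRNOG00000008465 showed no called difference between any mutant and WT, with log2 differences of 0.19 ± 0.19, 0.01 ± 0.19 and 0.31 ± 0.19. In all, 272 genes were called against WT in at least 1 mutant, 72 in the same direction in at least 2, and 20 in all 3 (17 lower and 3 higher than WT). With the replicate number as a block these numbers were 791, 220 and 57, and with DESeq2 671, 170 and 43. Without WT replicates 1, 2 and 3 in turn they were 552, 122 and 121, then 182, 37 and 32, then 68, 11 and 9. Genes in at least 2 mutants numbered 44 without R323 replicate 3. Genes in all 3 numbered 32 without R149 replicate 1, 11, 8 and 8 without R158 replicates 1, 2 and 3, and 13 without R323 replicate 2 or 3.

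The mutant contrasts share the WT libraries, so their overlap was set beside chance. R149 and R323 shared 47 lower and 8 higher genes, where independent lists would share 0.77 and 0.086. R149 and R158 shared 20 lower and 5 higher genes (0.43 and 0.074), and R158 and R323 shared 24 and 8 (0.24 and 0.13). Simulated mutants identical to WT shared at most 0.05 genes on average. They made at most 0.2 calls each on average, so this cannot show what the shared WT libraries contribute. With the replicate number as a block, 126 lower and 33 higher genes were shared by R149 and R323, 74 and 25 by R149 and R158, and 60 and 16 by R158 and R323. Without WT replicate 1 the lower genes shared numbered 112, 83 and 71 for these pairs, in this order. For R149 with R323 they were 28, 25, 28 and 26 without WT replicate 2 or 3 or R323 replicate 2 or 3. For R149 with R158 they were 10, 7, 12, 7 and 7 without WT replicate 2 or 3 or R158 replicate 1, 2 or 3, and 35 without R149 replicate 1. For R158 with R323 they were 15, 9, 15, 7 and 12 without WT replicate 2 or 3 or R158 replicate 1, 2 or 3. The higher genes shared ranged from 2 to 18, 1 to 19 and 2 to 15 with 1 library left out. The covariance of log2 fold changes was 0.142, 0.134 and 0.117 for these pairs in the order R149 with R323, R149 with R158, and R158 with R323, beside 0.0428, 0.0431 and 0.0433 in simulation. The correlations were 0.598, 0.575 and 0.52, beside simulated values of 0.502, 0.491 and 0.472. The sign was the same for 58.5%, 68.7% and 54.7% of all genes, where simulation gave 66.7%, 66.5% and 66.1%, so that 2 of the 3 pairs lay below it. The simulated libraries had no shared replicate effect, although libraries of equal number correlated among the MYC lines. The simulated values may therefore not be the right baseline for these pairs. The 3 WT libraries were too few to be split, so part of this overlap may come from the shared WT libraries.

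The mutants were compared with each other to ask whether the substitutions differed in effect. R149 differed from R158 in 174 genes, 37 higher and 137 lower in R149, with 16 and 76 by at least 2-fold. R149 differed from R323 in 147 genes, 25 higher and 122 lower in R149, with 14 and 47 by at least 2-fold. R158 differed from R323 in 128 genes, 79 higher and 49 lower in R158, with 44 and 19 by at least 2-fold. None of the 4 genes shown by identifier was called in these contrasts. The blocked fits called 92 genes higher and 289 lower for R149 with R158, 68 and 234 for R149 with R323, and 260 and 211 for R158 with R323. By at least 2-fold, these fits called 142, 91 and 108 genes in the same order. Without R149 replicate 2 or 3, the R149 and R158 contrast had 69 and 83 genes and the R149 and R323 contrast 71 and 55. Without R158 replicates 1, 2 or 3, the R149 and R158 contrast had 108, 97 and 93 genes. Without R323 replicate 2 or 3, the R149 and R323 contrast had 60 and 63 genes and the R158 and R323 contrast 31 and 38, and the latter had 40 without R158 replicate 2. The larger number higher in R158 than in R323 turned without R323 replicate 1 (74 higher and 84 lower) and was level without R323 replicate 3 (19 and 19). Genes with at least 2-fold difference numbered 46, 53, 54 and 54 for R149 with R158 without R149 replicate 2 or 3 or R158 replicate 2 or 3, from 92. They numbered 37 for R149 with R323 without R149 replicate 3 or R323 replicate 2 or 3, from 61, and 23, 25 and 28 for R158 with R323 without R158 replicate 2 or R323 replicate 2 or 3, from 63.

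**Figure D4:**
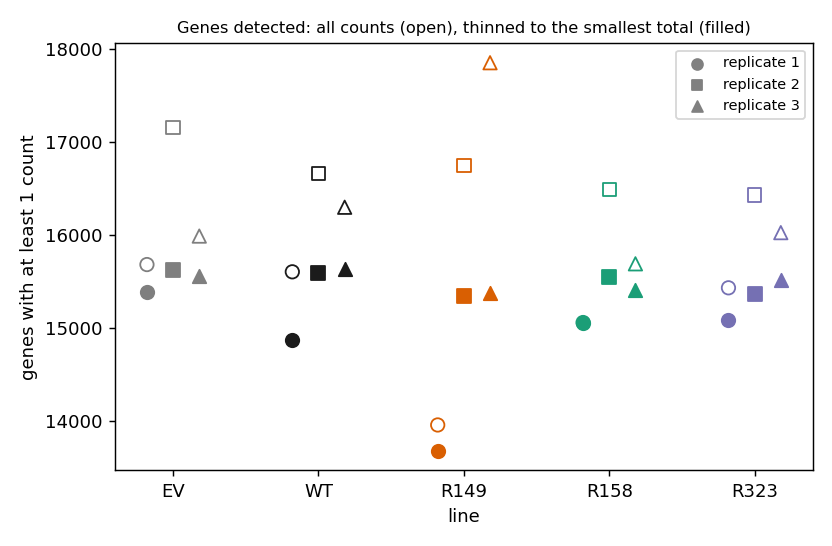
Genes with at least 1 count in each library, from all counts (open markers) and after thinning to the smallest total (filled markers). R149 replicate 1 lies lowest at 13677 genes after thinning, and the other 14 libraries lie between 14871 and 15636.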

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

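The tests of depth, of abundant genes, of the line itself, of the R149 to WT ratio and of genes distinct to a line were chosen after the result was seen; the test of low-count genes and the counts over other splits of the libraries were chosen before, but their restriction to splits that part the pairs after.

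The change against EV differed between lines, by the direct test of the difference, for 162 genes between R149 and WT, 82 between R158 and WT, 122 between R323 and WT, 174 between R149 and R158, 147 between R149 and R323, and 128 between R158 and R323. EV cancels in this difference, so these are the calls between lines already given and no further evidence. For ENSRNOG00000052880 the log2 change against EV minus that in WT was -10.7 in R149, -9.13 in R158 and -9.76 in R323. Single outlying values were not tested within the groups of 3 libraries; quality weights estimated from all 15 libraries were lowest for R149 replicate 1, at 0.158.

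R149 replicate 1 had fewer genes detected than any other library. Lower depth was argued against, since 13677 genes remained after thinning where the lowest other library had 14871, and so was a share taken by few genes, since its 10 most abundant genes held 4.89% of counts where the highest other library had 6.38%. The line itself was argued against too, because the better of R149 replicates 2 and 3 had 15374 genes after thinning. Genes with 1 to 5 thinned counts in replicates 2 and 3 kept a summed count of 0.825 of theirs in replicate 1, while 63.2% of them were at 0 there, against 32.7% to 42.7% in the other lines. The summed count ranged from 0.774 in WT to 1.18 in EV over the other lines, so the 0.825 was not particular to R149. Genes with exactly 1 count after thinning numbered 354 in R149 replicate 1, against 826 to 1221 in the other libraries. Few distinct molecules read many times in R149 replicate 1 could give this pattern, which remains a hypothesis without the reads. WT replicate 1 came next in genes detected, with 14871 after thinning and a quality weight of 0.252. Of genes with 1 to 5 thinned counts in WT replicates 2 and 3, 42.7% were at 0 there. Without WT replicate 1 the calls against WT numbered 356 in R149, 206 in R158 and 242 in R323. Whether the quality of that library accounts for these numbers was not tested.

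R149 against EV had 1.44 times as many called genes as WT against EV. Depth was argued against, because the ratio was 1.44 after thinning. Without R149 replicate 1 the ratio was 1.07, where leaving out R149 replicate 2 or 3 gave 1.35 and 1.29 and leaving out WT replicate 1, 2 or 3 gave 2.07, 1.87 and 1.55, so that the ratio fell or rose with the line that lost a library, but with replicates 2 and 3 alone in every line, a fit brought into this reading after the 1.07 was seen, it was 1.26. Whether that library may account for the excess stays open, since the values fall on both sides of the bound of 1.2 set for this test. A stronger response in the K149R line is the biological explanation, also open.

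Genes that differed between WT and all 3 mutants numbered 20 and could be read as needing all 3 lysines. Each mutant line also had genes that differed from all 3 other MYC lines, 19 in R149, 14 in R158 and 18 in R323, and the WT number was 1.05 times the highest of these. Over 24 alternatives that ratio ranged from 0.421 without R158 replicate 2 to 2.72 without WT replicate 1, and it was over the bound of 1.5 in 2 of them, the other being replicates 2 and 3 alone (272 genes in WT, at most 147 in a mutant, 1.85 times). Variation between stable lines that is unrelated to the substitutions and an effect of wild-type MYC that every substitution removes cannot be told apart, since the values fall on both sides of the bound and each construct had 1 line. ENSRNOG00000052880 is 1 of the 20 genes.

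For every comparison, the 10 ways to split the 6 libraries into groups of 3 were each fitted, and 1 split, the real one, gave the most called genes. The real split called 3656 genes for WT against EV, 5240 for R149, 3642 for R158 and 4676 for R323, and the highest other split called 0 in each. Against WT it called 54 genes for R149, 43 for R158 and 63 for R323, again with 0 as the highest other. Between mutants it called 42 genes for R149 and R158 and 98 for R149 and R323 (highest other 0), and 71 for R158 and R323 (highest other 2). Every other split puts libraries of both lines into each group, so a difference between lines adds to the spread within groups and lowers the calls. The low numbers of those splits therefore do not show how many calls a random grouping would give. With 10 splits no share can be below 0.1. In the 6 comparisons among MYC lines, where libraries of equal number correlated, 4 of the 10 splits part all 3 pairs of equal number, so that no share can be below 0.25, and the other 3 of these called 0 genes in each comparison. The other 6 splits part 1 pair, and their highest number was 0, except 2 for R158 and R323.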

How the results depend on the processing

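Alternatives chosen after seeing the data were replicates 2 and 3 alone, thinning, sample quality weights, fits without R149 replicate 1 for contrasts that do not use it, and WT against EV without R149 replicates 2 and 3 and R149 against EV without each WT replicate; so were all alternatives for genes shared by a pair of contrasts or by all 4 lines except library size alone, all for genes called in at least 1, 2 or 3 mutants or distinct to a line, left-out EV libraries for WT-regulated genes, and for the response score other filters and left-out EV or gene-choosing libraries. The others were chosen before. Gene list tests, and their alternatives, were not run because identifiers had no symbols. Counts against EV stayed within 1.5 times under DESeq2, limma-voom, every scaling, both filters, separate fits, thinning, replicates 2 and 3 alone, and the replicate block (2363 higher and 2621 lower for WT, 3162 and 3429 for R149, 2693 and 2641 for R158, 2565 and 2758 for R323, lines that did not pass the correlation check with EV). They left that range with sample quality weights (6850 for WT, 8917 for R149, 8733 for R323) and with 1 library left out, at 2399 to 4228 for WT and 2108 to 4436 for R158, lowest without EV replicate 3. Genes with at least 2-fold change in R158 against EV numbered 1320 with replicates 2 and 3, from 877. No scaling moved the share of higher calls by over 10 points, but the order of higher and lower calls for R158 against EV turned in 14 of 19 alternatives, among them every other scaling. When few genes changed in simulation, 1.5-fold changes were often missed, a share that does not carry over to the contrasts with EV.

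Counts among MYC lines moved too, given here in the order R149, R158, R323 against WT, then R149 with R158, R149 with R323, R158 with R323. DESeq2 called 396, 228, 270, 334, 287 and 424. The replicate block, used where libraries of equal number correlated, called 132 higher and 378 lower, 117 and 127, 144 and 179, 92 and 289, 68 and 234, and 260 and 211, and kept every gene of the unblocked fits. Replicates 2 and 3 alone called 1323, 996, 924, 627, 547 and 1274, and sample quality weights 1617, 283, 1603, 393, 3790 and 901. Fits of only the 2 lines compared called 54, 43, 63, 42 and 71, leaving out R149 with R323, which stayed within 1.5 times at 98. Limma-voom called 52 for R158. Leaving out 1 library gave 76 to 356, 19 to 206, 61 to 242, 69 to 141, 55 to 134 and 31 to 188. Numbers with at least 2-fold change, from 109, 53, 86, 92, 61 and 63, ranged over the alternatives other than left-out libraries from 38 to 446, 30 to 314, 53 to 327, 34 to 217, 35 to 317 and 48 to 260, and with 1 library left out from 60 to 218, 17 to 116, 52 to 157, 46 to 85, 37 to 74 and 23 to 74. Quality weights turned the order of higher and lower genes for R149 against EV (4506 and 4411), R158 against WT (166 and 117), R323 against WT (865 and 738) and R149 with R323 (1933 and 1857). Fits of only 2 lines estimate the spread from fewer libraries by construction, and otherwise the cause was not tested.

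WT-regulated genes that differed in R149, R158 and R323 numbered 112, 90 and 80 with DESeq2, 138, 97 and 92 with the replicate block, 347, 284 and 250 with replicates 2 and 3, and 300, 116 and 289 with quality weights, 151 of the 300 along the WT change. Limma-voom gave 28 for R158, and the fit of only the lines compared 22 for R149. Leaving out 1 library gave 30 to 105, 15 to 87 and 34 to 85.

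Overlaps of calls in all 4 lines against EV ranged up to 1946 higher and 2062 lower with quality weights. Genes called against WT in at least 1 and at least 2 mutants, from 272 and 72, numbered 671 and 170 with DESeq2, 791 and 220 with the replicate block, 2120 and 813 with replicates 2 and 3, 2629 and 717 with quality weights, and 123 and 27 in fits of only 2 lines. Lower and higher genes shared by R149 and R323 against WT, from 47 and 8, numbered 94 and 26, 126 and 33, 369 and 162, 384 and 264, and 17 and 2 under these settings in the same order. For R149 and R158, from 20 and 5, they were 57 and 16, 74 and 25, 335 and 155, 92 and 60, and 12 and 1, and for R158 and R323, from 24 and 8, 52 and 11, 60 and 16, 223 and 113, 86 and 63, and 13 and 2.

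The response score relative to WT moved with genes chosen from WT against EV, to -0.694, -0.697 and -0.635 over raised genes in R149, R158 and R323 and to -0.208, 0.291 and -0.00489 over lowered genes, from -0.54, 0.0271 and -0.283. That choice uses the WT libraries, which by construction favours WT, while the choice from the other mutants leaves out genes that WT alone changed. Over lowered genes the score was -0.284 in R149 and -0.105 in R323 with no fold minimum, and with 1 library left out it was -0.755 to -0.33 in R149, -0.165 to 0.124 in R158 and -0.491 to -0.142 in R323. Over raised genes in R323 it was 0.0245 with no fold minimum, and 0.0893 to 0.233 with 1 library left out. Every call made for the 4 shown genes against EV held in all 18 alternatives. ENSRNOG00000052880 was not called against EV in any mutant line, nor in any of 17 alternatives for each. ENSRNOG00000052880 lost its call in limma-voom against WT for R158 and R323, where its log2 differences were still -8.79 and -9.79. ENSRNOG00000014979 (R158 against WT) and ENSRNOG00000052758 (R149 against WT) gained one under some alternatives. For ENSRNOG00000052758 the log2 difference was 2.32, with an edgeR adjusted p of 0.136. It was called in 2 of 18 alternatives, the replicate block (2.37, edgeR adjusted p 0.0303) and DESeq2 (adjusted p 0.012).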

Other observations

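The comparison of scores by replicate number and the counts of genes that differed from WT and also from another mutant were chosen after the values were seen; the counts of genes called against WT were chosen before.

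Genes lower in the MYC lines than in EV varied with the replicate number inside all 4 MYC lines. Over the 499 genes lowered in R158 and R323, the score of replicate 1 was -2.11 in WT, -2.65 in R149, -2.03 in R158 and -2.25 in R323, while replicates 2 and 3 stood at -1.59 and -1.47 in WT, -2.07 and -2.08 in R149, -1.75 and -1.72 in R158, and -2.03 and -2.02 in R323. R158 and R323 are the lines in which these genes were chosen. Replicate 1 was the lowest in EV too, at -0.125 beside 0.0182 and 0.107. Genes with 1 to 5 thinned counts in replicates 2 and 3 were also lower in replicate 1 of the 4 MYC lines. Their summed count in replicate 1, relative to the mean of replicates 2 and 3, was 0.774 in WT and 0.825 in R149. It was 0.828 in R158 and 0.891 in R323, but 1.18 in EV. Their median ratio was 0.4 in WT, 0 in R149, 0.571 in R158, 0.667 in R323 and 0.75 in EV. In EV the summed and median ratios thus pointed in opposite directions. Whether the shift of the lowered genes is part of the lower detection in the MYC lines was not tested. Over raised genes the differences between libraries of equal number went both ways in every mutant.

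The genes that separated mutants from WT were lower in the mutant more often than higher in R149, at 136 of 162, and the 136 had a median log2 difference of -1.71. In R158 the edgeR fit called 39 higher and 43 lower, and the balance moved under other settings, to 71 and 135 without WT replicate 1 and 33 and 19 with limma-voom, with the order turned in 6 of 19 alternatives. Among genes lower in R149 than in WT, 51 were also lower than in R158 and 31 were also lower than in R323. Among the 39 genes higher in R158 than in WT, 20 were also higher than in R149 and 16 higher than in R323. In the other direction, of 26 genes higher in R149 than in WT, 3 were also higher than in R158 and 4 than in R323. Of 43 genes lower in R158 than in WT, 9 were also lower than in R149 and 5 than in R323. The same libraries of a mutant enter all of its contrasts, so part of this agreement may come from them.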
